A study of Mus musculus with 13 samples.

How the data were processed

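Per the labels' protocols, total RNA was extracted from mouse enterocytes with Trizol, labelled with biotin and hybridized to Affymetrix expression arrays, with 2 biological replicates in each group. The table holds 13 arrays and 35556 probe sets. Per the labels, the authors extracted the intensities with Affymetrix Expression Console 1.1 by its RMA Sketch method and then normalized them by the median intensities. The deposited values were read as log2 intensities. The labels do not state the base of the logarithm, which was taken from the values: they have a median between 4.96 and 5.12 on every array, the range of RMA values on a log2 scale. All values of the table belong to the 13 arrays of the series. No sequencing reads, genome sequence or aligner were involved. For arrays of this kind, their number limits the precision.

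Gene symbols came from the annotation table of the array platform. Of the probe sets, 21789 carried 1 gene symbol, 1621 carried several and 12146 carried none. Probe sets with several symbols or none were not named as genes and entered no gene test. The 19938 genes left included 999 with more than 1 probe set, for which the probe set with the highest mean over the 12 tested arrays was used. A gene was tested when at least 2 of these arrays exceeded the array's own 25th percentile, which left 16721 genes. The symbols of 16665 of them were matched through their Entrez numbers to the RefSeq gene table of GRCm38.p6, and 0 had another symbol there. That table was used for names and, through the order of its positions, for which genes neighbour each other; no coordinates are given.

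The 12 arrays named replicate 1 or 2 in their titles were fitted together with limma 3.58.1 in R 4.3.3, with 1 coefficient for each of the 6 groups and 6 residual degrees of freedom. The remaining array is titled as the third CKIα KO/p53 KO replicate, but its genotype and source labels name a CKI knockout alone. It was left out of the fit because these labels disagree, and was added in an alternative. For 10 comparisons, empirical Bayes moderated statistics gave a two-sided p-value per gene, which was adjusted by the method of Benjamini and Hochberg within each comparison. A gene was called at an adjusted p under 0.05. The comparisons were CKIα KO against CKIα Het with p53 and p21 present, with p21 knocked out and with p53 knocked out, the average of these, the difference of the CKIα effect between each knockout and the mice with both genes, and each p53 or p21 knockout group against its counterpart with both genes. Errors are the standard errors of the fit. Overlaps between called lists were tested with a one-sided Fisher's exact test over the tested genes.

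Gene sets were tested with camera of limma, with a preset correlation between genes of 0.01 and again with an estimated correlation, and p-values were adjusted over the 21 lists within a comparison. The lists hold 409 members. They cover Wnt/β-catenin targets, p53 targets, cell cycle, DNA damage response and repair, inflammation and secreted factors of senescence, interferon response, invasion and mesenchymal genes, the destruction complex and CK1 family, xenobiotic and drug metabolism, and lipid absorption and cholesterol. The others are markers of absorptive enterocytes, crypt base stem cells, Paneth cells, goblet cells, enteroendocrine cells, tuft cells, fibroblasts and smooth muscle, lymphocytes, myeloid cells, endothelial cells and red blood cells. The Wnt list shares 5 members with the crypt base list, 1 with the invasion list and 1 with the Paneth list. Counts of list members are given over all genes and adjusted over the list alone.

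The groups, comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names, in each comparison, up to 10 called genes with the largest and up to 10 with the most negative log2 fold change, the targeted genes, and up to 4 members of each list with the smallest p. Symbols of the predicted-gene, Riken, accession, olfactory, vomeronasal, immunoglobulin and T cell receptor types were passed over. Where fewer than 5 genes were called, the 10 genes with the smallest p were named as not passing.

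The alternatives were no filter on dim genes, a further quantile normalization of the 12 arrays, an intensity trend in the empirical Bayes step, the replicate number as a block, the third array added, and each array left out in turn.

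The test was run on simulated data with the real mean and the fitted spread of each gene, in which 200 of 16721 genes were changed, over 10 runs. Values were drawn independently and with the same spread on all arrays, as the test assumes. On the real arrays the replicate SD differed between groups, from 0.204 (CKIα Het) to 0.341 (CKIα KO/p21 KO). The shares below therefore check the computation and do not measure errors on the real arrays. For CKIα KO against CKIα Het, 67.8% of the genes changed by a log2 of 1 and 97.1% of those changed by a log2 of 2 were recovered, and 4.18% of the calls were false. For the comparison with p53 knocked out these shares were 68.8%, 97.2% and 5.57%. With 20% of the genes changed by a log2 of 1, 92% were recovered and 3.72% of the calls were false. In 50 simulated runs of camera on 25 independent genes with the preset correlation, 1 unshifted list and all 50 lists shifted by 0.5 had a p under 0.05. The version with an estimated correlation was not simulated. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.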

Results

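Casein kinase Iα (CKIα, gene Csnk1a1) is a kinase of the complex that marks β-catenin, the effector of Wnt signalling, for degradation. Its gene was knocked out in the gut of mice, and the mice were crossed with animals lacking p53, a transcription factor and tumour suppressor, or p21, a cell cycle inhibitor that p53 activates. Expression was measured in enterocytes on 13 arrays. The 6 groups were heterozygous (CKIα Het) or homozygous (CKIα KO) for the gut knockout, each with p53 and p21 present, with p21 knocked out or with p53 knocked out. Each group had 2 arrays, which the labels call biological replicates. The p-values rest on the spread between replicates, pooled over the 6 groups, and not on the spread within the groups compared. The remaining array is titled as the third CKIα KO/p53 KO replicate, while its genotype and source labels name a CKI knockout alone, and it entered none of the comparisons. The median log2 intensity per array lay between 4.96 and 5.12.

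The CKIα Het arrays of all backgrounds lay together on the first principal component of 16721 genes, which carried 50.1% of the variance, between -31.0 and -19.8. The CKIα KO/p53 KO arrays lay at 43.0 and 51.2, the CKIα KO/p21 KO arrays at 5.30 and 52.4, and the CKIα KO arrays at -14.4 and 11.2. Iron reductase Cybrd1 had log2 values of 7.72 and 11.81 on the CKIα KO arrays, an example of the spread within that group. Across genes, replicates of a group had correlations from 0.971 (CKIα KO/p21 KO) to 0.990 (CKIα Het), and 781 and 138 genes differed by more than 2-fold between the replicates of these groups. Genes are not independent replicates in such a correlation. Xist, the RNA of the inactive X chromosome, was chosen after its values were seen. It lay between 3.15 and 3.94 on the 6 replicate 1 arrays and between 8.91 and 10.1 on the 6 replicate 2 arrays. With the Y-linked genes given further below, this is the pattern of male mice for replicate 1 and of female mice for replicate 2. The labels do not give sex. Each group thus held 1 array of each kind. The spread between replicates therefore includes any difference between these kinds. With this kind as a term in the limma fit, which removes a shift that all groups share, counts moved by more than 1.5 times only where that is said.

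**Figure D1:**
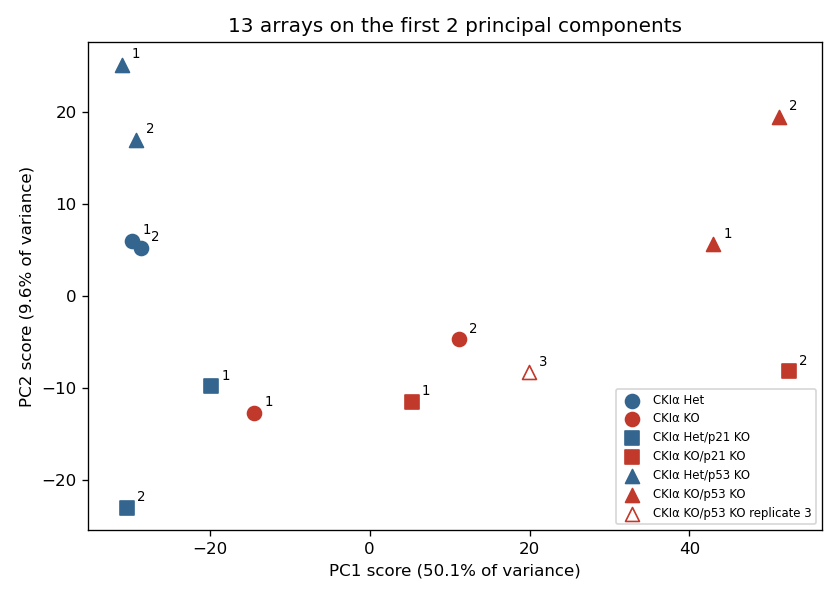
First against second principal component (50.1% and 9.6% of the variance) of the 13 arrays, 1 point per array; colour gives the CKIα genotype, marker shape the p53 or p21 background, and the open marker the third array titled CKIα KO/p53 KO. The CKIα Het arrays sit at or below -19.8 on the first component, and the arrays homozygous for the CKIα knockout at or above -14.4.

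Csnk1a1 itself, the targeted gene, had log2 values between 10.45 and 10.80 on all 13 arrays. It was -0.05 ± 0.13 (log2, SE, n = 2 per group) in CKIα KO against CKIα Het, 0.14 ± 0.13 with p21 knocked out and -0.05 ± 0.13 with p53 knocked out, and passed in none of these limma tests (adjusted p = 0.959, 0.594 and 0.805). After a further quantile normalization the second value was -0.06, and without CKIα KO/p53 KO replicate 1 the last was 0.06. The probe set covers the whole gene, and the labels do not say which exons are deleted, so this value checks no genotype. Trp53, the p53 gene, and Cdkn1a, the p21 gene, are not given as genes: the annotation names no probe set for the first and puts the second on a probe set with another gene.

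The comparison of CKIα KO with CKIα Het asked what the loss of CKIα changes while p53 and p21 are present. Duoxa2 and Duox2 encode the maturation factor and the enzyme of an epithelial oxidase that releases hydrogen peroxide. Duoxa2 rose 16.2-fold (log2 4.02 ± 0.33, SE, n = 2 per group, adjusted p = 0.00381) and Duox2 rose 14.6-fold (3.87 ± 0.33, adjusted p = 0.00381). The zinc finger gene Zfp37 rose 3.13-fold (adjusted p = 0.0459). The remaining called gene, 4930402H24Rik, was named after its values were seen, and rose by a log2 of 1.47 ± 0.16 (adjusted p = 0.0223). Akr1b8, an aldo-keto reductase, was at 3.50 ± 0.45 (adjusted p = 0.0516), and Nox1, another epithelial oxidase, at 3.09 ± 0.44 (adjusted p = 0.0803), and neither passed. In all, limma called 4 genes higher and 0 lower, and 1520 genes had an unadjusted p under 0.05. Without CKIα Het replicate 1 or CKIα KO replicate 2, 0 genes were called, and without CKIα KO replicate 1, 57 were higher and 7 lower. A further quantile normalization left 2 genes higher, as did adding the third array and fitting the kind of array that Xist parts.

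Among the Wnt/β-catenin targets in CKIα KO, Axin2, a feedback inhibitor of the pathway, was at 1.30 ± 0.23 (adjusted p = 0.106) and the cyclin Ccnd2 at 1.45 ± 0.32 (adjusted p = 0.186). Of the 26 measured targets 0 passed over all genes and 2 were higher when adjusted over the list alone, with a median log2 of 0.40. Of 27 p53 targets 0 passed over all genes and 4 were higher adjusted over the list alone, with a median of 0.29. These included Ccng1, a cyclin that p53 induces (1.43 ± 0.23, adjusted p = 0.0972), and Eda2r, a member of the TNF receptor family (1.90 ± 0.38, adjusted p = 0.146). The cell cycle list had a median of 0.05 over 29 genes. The goblet cell markers had a median of -0.49 and the enteroendocrine markers of -0.69, with 0 members of either called over all genes and 2 and 3 lower adjusted over the list alone. Somatostatin (Sst), an enteroendocrine hormone, was at -2.28 ± 0.47 (adjusted p = 0.161). Paneth cell markers had a median of -0.67, xenobiotic genes of -0.43, myeloid markers of -0.24 and interferon response genes of 0.31. Of the 21 lists, 8 passed camera with the preset correlation and 0 with an estimated correlation. With an estimated correlation, the adjusted p was 0.391 for p53 targets, goblet and enteroendocrine markers and 0.63 for Wnt targets, Paneth and myeloid markers, xenobiotic and interferon genes.

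With p21 knocked out, CKIα KO was compared with CKIα Het to ask what its loss changes without the p53 target p21. Eda2r rose 13.3-fold (3.74 ± 0.38, n = 2 per group, adjusted p = 0.00928) and Nox1 16.0-fold (adjusted p = 0.00928). The iron genes Cybrd1, which reduces dietary iron, and Slc40a1, the iron exporter ferroportin, rose 25.6-fold and 11.4-fold (adjusted p = 0.0497 and 0.0485). Psrc1, a microtubule protein of the spindle, rose 8.37-fold, Ephx1, an epoxide hydrolase, 9.28-fold and Cfi, a regulator of complement, 5.42-fold. Slc5a4a, of the sodium and glucose cotransporter family, was 8.18-fold lower (-3.03 ± 0.56, adjusted p = 0.0434), and Ido1, a tryptophan-degrading enzyme, 7.89-fold lower (-2.98 ± 0.56, adjusted p = 0.0440). The incretin hormone Gip was 5.81-fold lower (-2.54 ± 0.53, adjusted p = 0.0481).

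In that comparison without p21, 12 of 27 p53 targets rose over all genes and 16 adjusted over the list alone, with 0 lower and a median of 0.86. Zmat3, an RNA-binding p53 target, rose 4.61-fold, Ccng1 4.25-fold and the death receptor Tnfrsf10b by a log2 of 1.47 ± 0.18. Of 26 Wnt targets 2 rose over all genes, Axin2 (1.92 ± 0.23, adjusted p = 0.0140) and Rnf43, a ligase that removes Wnt receptors (1.72 ± 0.32, adjusted p = 0.0434), and 11 adjusted over the list alone. The adjusted p was 0.249 for p53 targets and 0.317 for Wnt targets with an estimated correlation. Of 29 cell cycle genes 3 rose over all genes and 24 adjusted over the list alone, among them the replication licensing gene Mcm2 (1.29 ± 0.21) and the mitotic kinases Bub1 (1.62 ± 0.30) and Plk1 (1.40 ± 0.28). Of 20 DNA damage genes, the checkpoint kinase Chek2 rose over all genes (1.41 ± 0.30) and 14 adjusted over the list alone. Both lists had an adjusted p of 0.28 with an estimated correlation. Of 14 crypt base markers 1 rose over all genes and 7 adjusted over the list alone (median 0.91, adjusted p = 0.32 with an estimated correlation).

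Lower without p21 were 4 of 19 enteroendocrine markers over all genes and 17 adjusted over the list alone, with a median of -0.93, among them Chga, a granule protein (-1.45 ± 0.25). Of 14 goblet markers 2 fell over all genes, Atoh1, the factor that specifies secretory cells (-1.23 ± 0.17), and Tff3, a mucus peptide (-1.50 ± 0.30), and 9 adjusted over the list alone. With an estimated correlation the adjusted p was 0.249 for enteroendocrine and 0.28 for goblet markers. Of 13 tuft markers 1 fell over all genes and 3 adjusted over the list alone (median -0.26, adjusted p = 0.28 with an estimated correlation). The absorptive enterocyte markers had a median of -0.66 with 0 of 23 called over all genes or adjusted over the list alone (adjusted p = 0.32 with an estimated correlation). Lymphocyte, fibroblast and myeloid markers, of cells outside the epithelium, had medians below 0 beside these, with no member called over all genes. The lymphocyte markers had a median of -1.27 with 0 of 15 called over all genes and 14 lower adjusted over the list alone. Fibroblast and smooth muscle markers had a median of -0.75, with a smallest unadjusted p of 0.0563 by limma (Dcn), and myeloid markers one of -0.50 (adjusted p = 0.28 for each list with an estimated correlation). Lipid genes had a median of -0.41 with 0 called (adjusted p = 0.494 with an estimated correlation). Of the interferon list, the immunoproteasome subunit Psmb8 fell (-1.19 ± 0.19).

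In all, limma called 244 genes higher and 86 lower without p21, 3881 had an unadjusted p under 0.05, and the adjusted p of the calls had a median of 0.0459, close to the threshold. A further quantile normalization gave 143 higher and 82 lower, the fit without the filter on dim genes 126 and 37, and the fit with the third array 77 and 31. Without CKIα Het/p21 KO replicate 2, 0 genes were called, and without its replicate 1, 12 were higher and 6 lower. Without CKIα KO/p21 KO replicate 2, 11 were higher and 3 lower, and without its replicate 1, 1695 were higher and 1082 lower. The number called therefore changed with each of these arrays.

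With p53 knocked out, the same contrast asked what the loss of CKIα changes in its absence. Cybrd1 rose 87.1-fold (6.44 ± 1.01, n = 2 per group, adjusted p = 0.00771) and Slc40a1 rose 31.2-fold (4.96 ± 0.74, adjusted p = 0.00763). Plat, the tissue plasminogen activator, a protease, rose 18.9-fold (4.24 ± 0.46, adjusted p = 0.00427). The surface protein Ly6d rose 26.1-fold, the annexins Anxa1 and Anxa10 17.6-fold and 16.4-fold, and the lipid enzymes Mboat1 and Scd1 16.9-fold and 12.9-fold. Slc5a4a was 49.5-fold lower (-5.63 ± 0.56, adjusted p = 0.00341), the vitamin C transporter Slc23a1 43.6-fold lower (-5.45 ± 0.79, adjusted p = 0.00756) and lactase (Lct) 23.7-fold lower (-4.57 ± 0.94, adjusted p = 0.0141). Enpp7, an alkaline sphingomyelinase, was 37.7-fold lower.

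Of 26 Wnt targets, 17 rose without p53 over all genes and 21 adjusted over the list alone, with 0 lower and a median of 1.70 (adjusted p = 0.48 with an estimated correlation). The feedback inhibitors Axin2 (2.35 ± 0.23), Nkd1 (3.37 ± 0.42), Wif1 (1.65 ± 0.21) and Rnf43 (2.15 ± 0.32) were among them. Of 14 crypt base markers, 5 of which are also Wnt targets, 6 rose over all genes (median 0.99), and 9 were higher and 1 lower adjusted over the list alone (adjusted p = 0.483 with an estimated correlation). Of 29 cell cycle genes 19 rose over all genes and 25 adjusted over the list alone, including Mcm3 (1.66 ± 0.30) and Plk1 (1.45 ± 0.28). Of 20 DNA damage genes 13 rose over all genes and 16 adjusted over the list alone, including Brca1 (1.40 ± 0.26). Both lists had an adjusted p of 0.48 with an estimated correlation. The 27 p53 targets had a median of -0.19, and only Plk2, a stress kinase, rose (2.09 ± 0.48) and Sesn1, a stress protein, fell (-1.76 ± 0.41), the same 1 and 1 when adjusted over the list alone.

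In the invasion and mesenchymal list, which the title of the series puts in view, 3 of 21 genes rose without p53 over all genes, and 2 adjusted over the list alone. Mmp14, a membrane-bound matrix protease, rose 4.17-fold (2.06 ± 0.38, adjusted p = 0.0102), the adhesion receptor and Wnt target Cd44 rose 7.57-fold (2.92 ± 0.59, adjusted p = 0.0133) and the filament protein Vim rose 2.73-fold (1.45 ± 0.44, adjusted p = 0.0473). Mmp14 and Cd44 were also above 0 in the other backgrounds, without passing: 1.32 ± 0.38 and 2.70 ± 0.59 with p21 knocked out, and 0.91 ± 0.38 and 1.41 ± 0.59 with both genes. The rise of Mmp14, Cd44 and Vim was not shown to differ between mice without p53 and mice with both genes (limma interaction, adjusted p = 0.352, 0.416 and 0.266). The invasion list as a whole had a median of 0.04 without p53 and did not pass camera (adjusted p = 0.271). Of 22 genes of inflammation and senescence, 3 rose over all genes and adjusted over the list alone, namely Plat, the interleukin 1 antagonist Il1rn (2.77 ± 0.59) and the urokinase receptor Plaur (1.58 ± 0.38), with a list median of 0.05. Of 19 interferon genes Ifit2 rose (2.34 ± 0.48) and Psmb8 and Psmb9 fell, with a list median of 0.30. Of 12 genes of the destruction complex and CK1 family only Csnk1e rose (1.05 ± 0.25), with a list median of 0.03. Neither of these lists passed camera, and their counts adjusted over the list alone were the same.

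Of 23 absorptive enterocyte markers 13 fell without p53 over all genes and 17 adjusted over the list alone, with 0 higher and a median of -1.03, among them the peptidase Enpep (-1.85 ± 0.25) and the vitamin receptor Cubn (-4.05 ± 0.71). Of 19 enteroendocrine markers 10 fell over all genes and 14 adjusted over the list alone, including Sst (-2.78 ± 0.47). Of 14 goblet markers 6 fell over all genes and 7 adjusted over the list alone, including Clca1 (-2.33 ± 0.47). These 3 lists had an adjusted p of 0.48 with an estimated correlation. Of 21 xenobiotic genes 7 fell over all genes and 11 adjusted over the list alone, with a median of -0.99, among them the carboxylesterase Ces2a (-2.82 ± 0.42). Of 20 lipid genes 3 rose and 7 fell over all genes, and 4 and 9 adjusted over the list alone, with a median of -0.63. The adjusted p was 0.483 for the xenobiotic and 0.674 for the lipid list with an estimated correlation.

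**Figure D2:**
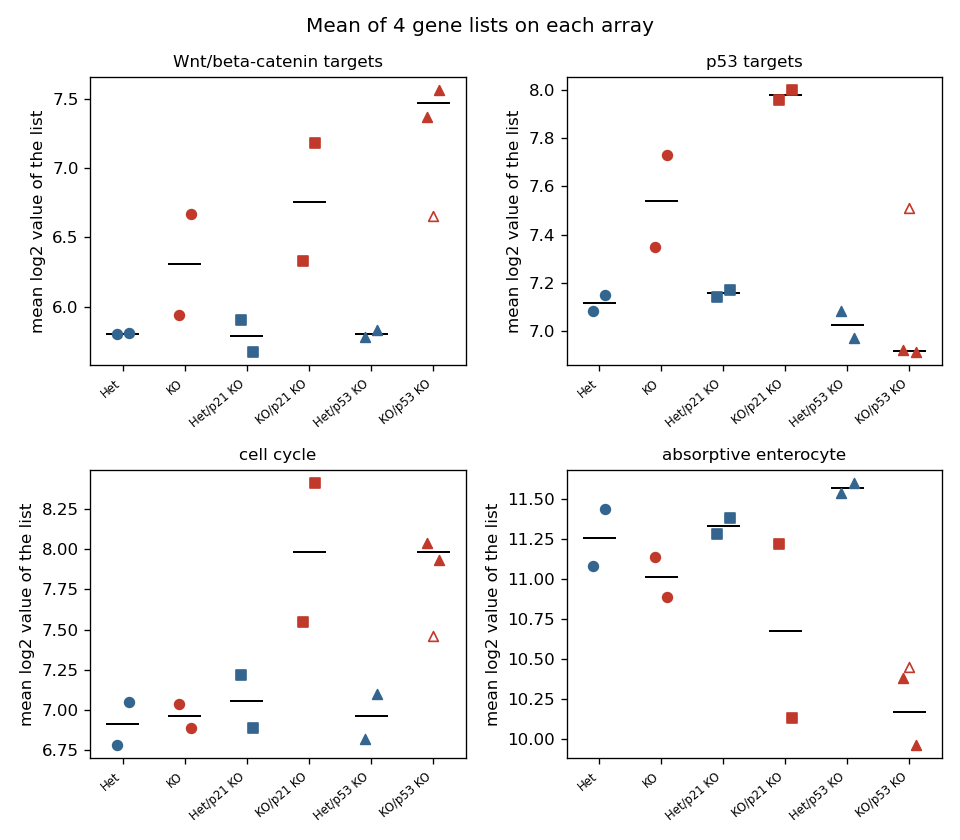
Mean log2 intensity per array of the measured Wnt/β-catenin targets, p53 targets, cell cycle genes and absorptive enterocyte markers, by group; points are arrays, black lines the means of replicates 1 and 2, and the open point the third array titled CKIα KO/p53 KO. The Wnt targets lie at 7.37 and 7.56 on the CKIα KO/p53 KO arrays and at 5.78 and 5.83 on the CKIα Het/p53 KO arrays, and the absorptive markers at 10.38 and 9.96 against 11.54 and 11.60.

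The lists of the remaining cell types did not pass camera without p53. Of 7 Paneth markers the protease Mmp7, also a Wnt target, rose (2.73 ± 0.54), with a list median of 0.48. Of 13 tuft markers Avil rose (2.40 ± 0.40) and Sh2d6 fell (-0.53), with a median of -0.28 and a mean of 0.14. Of 14 myeloid markers Cd68 (0.89) and Cd14 (0.81) rose, with a median of -0.08 and a mean of 0.09. Of 10 endothelial markers Eng fell (-0.44 ± 0.13), with a median of -0.14 and 2 lower adjusted over the list alone. By limma, 0 of 13 fibroblast and smooth muscle markers (median -0.22), 0 of 15 lymphocyte markers (-0.28) and 0 of 2 red blood cell markers (-0.06) passed. Adjusted over the list alone, 1 Paneth, 1 tuft and 2 myeloid markers were higher and 2 tuft markers lower.

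In all, limma called 1841 genes higher and 1140 lower without p53, and 5773 had an unadjusted p under 0.05. A further quantile normalization gave 1407 higher and 1369 lower. Without CKIα Het/p53 KO replicate 1, 10 were higher and 10 lower, and without its replicate 2, 402 and 253. Without CKIα KO/p53 KO replicate 1, 869 were higher and 452 lower, and without its replicate 2, 161 and 90.

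Averaged over the 3 backgrounds (6 arrays against 6), CKIα KO against CKIα Het gave their mean change, which need not hold in each. Cybrd1 was 37.0-fold (5.21 ± 0.58, adjusted p = 0.00192) and Slc40a1 16.0-fold higher, and Nox1 (3.27 ± 0.26) and Duoxa2 (2.82 ± 0.19) rose as well. Slc5a4a fell (-3.45 ± 0.32). Axin2 rose 3.62-fold (1.86 ± 0.13, adjusted p = 0.000707), and 19 of 26 Wnt targets and 24 of 29 cell cycle genes rose with it over all genes, 21 and 27 adjusted over the list alone. Of the p53 targets 13 rose and 1 fell over all genes, 14 and 3 adjusted over the list alone. Over all genes 14 of 23 absorptive, 9 of 14 goblet and 15 of 19 enteroendocrine markers fell (15, 10 and 17 adjusted over the list alone), beside 2 of 15 lymphocyte markers (0 adjusted over the list alone). Of 14 myeloid markers 2 rose, among them Cd14 (0.57 ± 0.12), and 3 fell, Tyrobp (-0.61 ± 0.17), Csf1r (-0.35) and Adgre1 (-0.40), and 2 and 6 did adjusted over the list alone. Of 13 tuft markers Avil rose (1.05 ± 0.23) and 4 fell, among them Sh2d6 (-0.59 ± 0.09) and Dclk1 (-0.46), and 1 and 5 did adjusted over the list alone, with a median of -0.17. The invasion list had 3 higher, among them Mmp14 (1.43) and Cd44 (2.34 ± 0.34), with a median of -0.09 and a mean of 0.13. With an estimated correlation the adjusted p was 0.419 for Wnt, p53, goblet and enteroendocrine lists 0.462 for cell cycle and absorptive lists and 0.507 for tuft and lymphocyte lists. In all, 12 of the 21 lists passed with the preset correlation and 0 with an estimated one.

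By limma 2585 genes were higher and 1499 lower in this average, and 2056 and 1914 after a further quantile normalization. Leaving out 1 array gave between 1694 and 3032 higher and between 960 and 1839 lower. The counts moved by more than 1.5 times without CKIα Het replicate 1 (987 lower and 1718 higher), CKIα Het/p21 KO replicate 2 (1694 higher and 972 lower), CKIα KO replicate 2 (960 lower) and CKIα Het/p53 KO replicate 1 (998 lower).

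**Figure D3:**
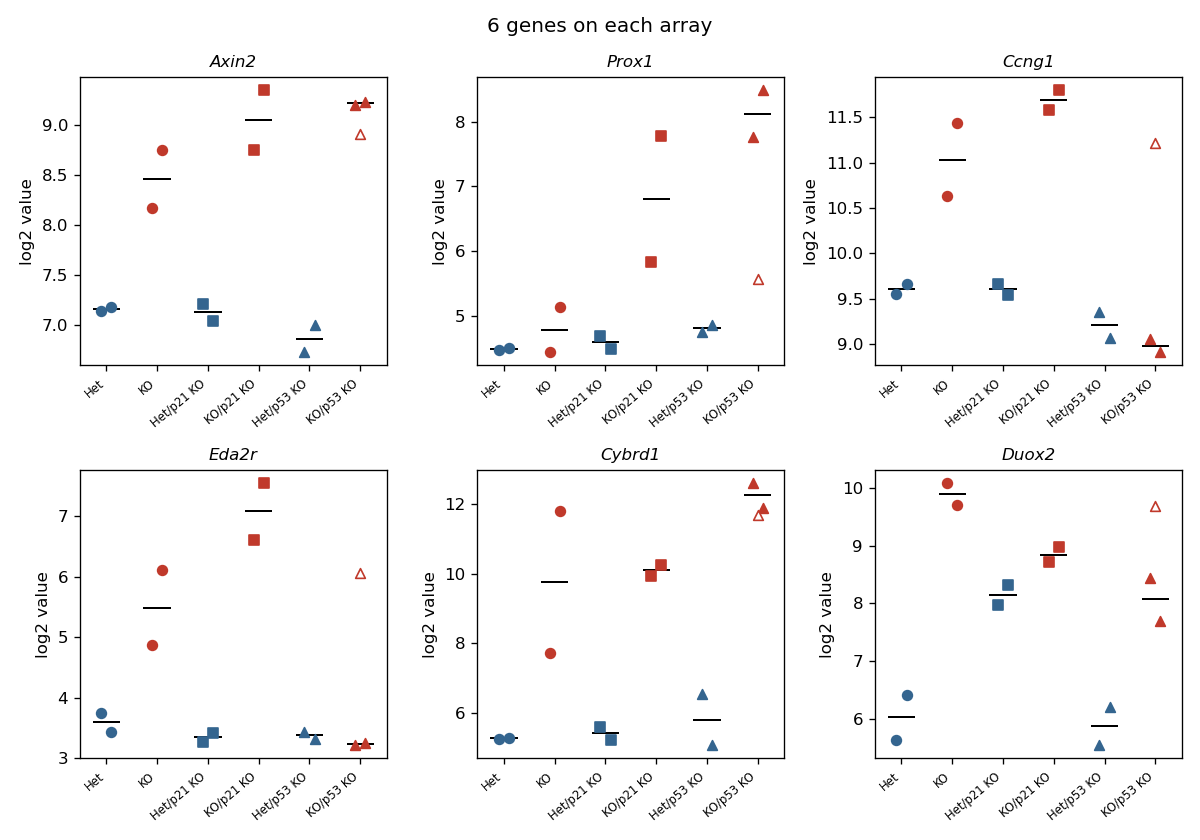
Log2 intensity per array of Axin2, Prox1, Ccng1, Eda2r, Cybrd1 and Duox2, by group; points are arrays, black lines the means of replicates 1 and 2, and the open point the third array titled CKIα KO/p53 KO. Ccng1 lies at 9.06 and 8.91 on the CKIα KO/p53 KO arrays and at 10.63 and 11.44 on the CKIα KO arrays, and Duox2 at 10.08 and 9.71 on the CKIα KO arrays against 5.64 and 6.41 on the CKIα Het arrays.

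Many of the genes called without p21 were also called without p53, in comparisons that share no arrays but share the standard error of each gene. Genes with a small spread are favoured in both lists, and genes are not independent of each other. The numbers for independent lists and the p-values of Fisher's test are therefore no measure of chance here. Of the higher genes 179 were in both lists where 26.9 would be shared by independent lists (Fisher's exact test, one-sided, p = 1.65e-118), and of the lower genes 46 where 5.86 would be (p = 3.58e-31). The 4 genes called with p53 and p21 present were all higher without p53 too (0.44 by independent lists, Fisher's exact test, one-sided, p = 0.000147), and 0 of the 4 were called without p21 (0.0584 by independent lists, Fisher's exact test, one-sided, p = 1). The 244 genes called higher without p21 had a median log2 of 1.17 there, 0.98 without p53 and 0.38 with both genes present, where 93% of them were above 0. One gene, Inka2, named after its values were seen, rose without p21 (0.93 ± 0.17) and fell without p53 (-0.57 ± 0.17). In all, 229 genes were called the same way in at least 2 of the 3 comparisons. Without 1 array this number was 3 (CKIα Het replicate 1, CKIα Het/p21 KO replicate 2 or CKIα Het/p53 KO replicate 1), 6 (CKIα Het replicate 2 or CKIα Het/p21 KO replicate 1), 7 (CKIα Het/p53 KO replicate 2 or CKIα KO/p53 KO replicate 2), 10 (CKIα KO/p53 KO replicate 1), 78 (CKIα KO/p21 KO replicate 2) or 1963 (CKIα KO/p21 KO replicate 1).

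The interaction asked whether the effect of CKIα loss differs between mice without p53 and mice with both genes. Cyp1b1, a cytochrome P450, changed by 2.72 ± 0.27 more without p53 (adjusted p = 0.0154), and the amino acid transporter Slc38a4 by 2.98 ± 0.36 more (adjusted p = 0.0496). Dglucy, the D-glutamate cyclase, changed by -2.45 ± 0.24 (adjusted p = 0.0154): it fell without p53 (-2.30 ± 0.17) and was at 0.15 ± 0.17 with both genes. The protease Plat was at 3.86 ± 0.66 and the Wnt antagonist Nkd1 at 2.99 ± 0.60 (adjusted p = 0.169 for both), and Ccng1 at -1.66 ± 0.33 (adjusted p = 0.169), so none of these was shown to differ. In all 2 genes were higher and 1 lower by limma, and 2485 had an unadjusted p under 0.05. The Wnt list had a median difference of 1.10, with 0 called over all genes and 8 higher adjusted over the list alone, and the p53 targets one of -0.40, with 0 called over all genes and 6 lower adjusted over the list alone. Cell cycle genes (median 1.00) had 16 higher adjusted over the list alone and 0 over all genes. The adjusted p was 0.406 for Wnt targets, p53 targets and cell cycle genes with an estimated correlation, and 8 of the 21 lists passed with the preset correlation and 0 with an estimated one. Without any 1 of the 4 arrays with both genes, or of the CKIα Het/p53 KO arrays, 0 genes were higher, and 17 were without CKIα KO/p53 KO replicate 1 and 4 without its replicate 2. Lower were 3 without CKIα Het replicate 2, 1 without CKIα KO/p53 KO replicate 1 and 0 without any other 1 of these arrays, and with the third array added 0 were higher and 0 lower. Without the filter 1 was higher, and with the kind of array that Xist parts as a term 1 was higher, while after quantile normalization 2 were lower.

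For p21 the same interaction had 0 genes higher and 0 lower by limma, with 1359 at an unadjusted p under 0.05. The smallest p belonged to Cfi (2.35 ± 0.35) and Duox2 (-3.17 ± 0.47), both with an adjusted p of 0.308. Mcm2 was at 1.34 ± 0.30 and Eda2r at 1.84 ± 0.53, and did not pass (adjusted p = 0.568 and 0.615). The cell cycle list had a median difference of 0.87 with 1 gene higher adjusted over the list alone and 0 over all genes (adjusted p = 0.433 with an estimated correlation), and the lymphocyte markers one of -0.96 (adjusted p = 0.447 with an estimated correlation). Of the 21 lists 12 passed with the preset correlation and 0 with an estimated one. Without CKIα KO/p21 KO replicate 1, 74 genes were higher and 34 lower, without its replicate 2, 1 was lower, and without CKIα Het replicate 2, 2 were lower.

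Among CKIα KO mice, those without p53 were compared with those that kept it, to show what p53 loss adds to CKIα loss. Plat rose 12.8-fold (3.68 ± 0.46, n = 2 per group, adjusted p = 0.0182) and Prox1, a transcription factor and Wnt target, rose 10.1-fold (3.34 ± 0.51, adjusted p = 0.0438). Slc38a4 rose 9.28-fold, Nkd1 6.98-fold and Cyp1b1 6.42-fold. Dglucy was 6.91-fold lower (-2.79 ± 0.17, adjusted p = 0.000366), and the p53 targets Eda2r and Ccng1 were 4.80-fold and 4.15-fold lower (-2.26 ± 0.38 and -2.05 ± 0.23). Duox2 fell too (-1.82 ± 0.33, adjusted p = 0.0472). Of 27 p53 targets these 2 fell over all genes and 12 adjusted over the list alone (median -0.64, adjusted p = 0.284 with an estimated correlation). Of 26 Wnt targets 3 rose over all genes and 17 adjusted over the list alone, Wif1 among them (1.78 ± 0.21), and of 29 cell cycle genes Mcm2 rose (1.22 ± 0.21) and 27 adjusted over the list alone, with medians of 1.23 and 0.99 (adjusted p = 0.378 for both with an estimated correlation). Absorptive markers had a median of -0.76 with 0 called over all genes and 8 lower adjusted over the list alone (adjusted p = 0.407 with an estimated correlation). Goblet markers had a median of -0.49 and enteroendocrine markers of -0.56, with 0 called over all genes and 7 and 6 lower adjusted over the list alone. Of the 21 lists 10 passed with the preset correlation and 0 with an estimated one. By limma 78 genes were higher and 38 lower, and 3727 had an unadjusted p under 0.05. Without CKIα KO replicate 1, 3 were higher and 4 lower, without its replicate 2, 170 and 71, and without CKIα KO/p53 KO replicate 2, 11 and 1. With the kind of array that Xist parts as a term 218 were higher and 120 lower, and with the third array added to the CKIα KO/p53 KO group 0 and 0.

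Among CKIα KO mice without p21 against those with it, Rab44, a small GTPase whose gene lies directly next to Cdkn1a, rose 11.9-fold (3.57 ± 0.22, adjusted p = 0.000374) and Cfi rose 6.84-fold (2.78 ± 0.25, adjusted p = 0.00529). The transporter Abcb1b (1.94 ± 0.24) and Stox2 (1.87 ± 0.20) rose, and Ceacam10, an adhesion family member, fell (-2.33 ± 0.27, adjusted p = 0.0214). Gm10044, named after its values were seen, also fell (-1.29 ± 0.15). These were all 4 higher and 2 lower genes by limma, and 2005 had an unadjusted p under 0.05. Of 29 cell cycle genes 0 passed over all genes and 29 were higher adjusted over the list alone, with a median of 1.00, and of 20 DNA damage genes 0 and 17, with a median of 0.88. Of 27 p53 targets 0 passed over all genes and 9 were higher adjusted over the list alone, with a median of 0.46. These 3 lists had an adjusted p of 0.296 with an estimated correlation. Markers of other cell types were lower beside them in median: lymphocyte markers had a median of -0.98, with 0 of 15 called over all genes or adjusted over the list alone, and enteroendocrine markers one of -0.57, with 0 of 19 called over all genes and 3 lower adjusted over the list alone (adjusted p = 0.582 and 0.368 with an estimated correlation). Gip was at -1.93 ± 0.53 (adjusted p = 0.241). Interferon genes had a median of -0.41 with 3 lower adjusted over the list alone, crypt base markers one of 0.56 with 4 higher, and Wnt targets one of 0.32 with 0 (adjusted p = 0.477, 0.391 and 0.582 with an estimated correlation). Xenobiotic genes (-0.47), absorptive (-0.35), goblet (-0.30) and tuft markers (-0.27) and lipid genes (-0.29) had 0 called either way. In all, 13 of the 21 lists passed with the preset correlation and 0 with an estimated one. Without CKIα KO replicate 1, 2 genes were higher and 7 lower, and without its replicate 2, 4 and 0. Without CKIα KO/p21 KO replicate 1, 761 were higher and 387 lower, and without its replicate 2, 2 and 1. With the kind of array that Xist parts as a term 1 was lower.

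Between CKIα Het mice without p21 and those with it, 1 gene differed by limma, and 837 genes had an unadjusted p under 0.05. This gene was Rab44, the neighbour of Cdkn1a, which was 6.77-fold higher without p21 (2.76 ± 0.22, n = 2 per group, adjusted p = 0.00421). Otop3, a proton channel, was at -1.52 ± 0.18 (adjusted p = 0.0822). The xenobiotic genes had a median of -1.18 with 0 called over all genes and 2 lower adjusted over the list alone, Gstm1 being at -2.24 ± 0.45 (adjusted p = 0.379), the fibroblast and smooth muscle markers one of 0.78 and the 7 Paneth markers one of -0.54, with 0 called either way. These 3 of the 21 lists passed with the preset correlation and 0 with an estimated one (adjusted p = 0.641, 0.567 and 0.773). Without CKIα Het replicate 1, 2 genes were lower, without its replicate 2, 0 were higher, and without CKIα Het/p21 KO replicate 1, 4 were higher. The loss of p53 in CKIα Het mice left 0 genes higher and 0 lower by limma, with 941 at an unadjusted p under 0.05 and 2 lower without CKIα Het replicate 1. The inflammasome gene Nlrp1b had the smallest p (-1.37, adjusted p = 0.788). With the preset correlation 8 of the 21 lists passed there, and 0 with an estimated one. Their medians were -0.32 for myeloid, -0.39 for Paneth, -0.31 for goblet, -0.23 for enteroendocrine and -0.08 for fibroblast and smooth muscle markers, -0.09 for DNA damage genes, and 0.28 for absorptive and 0.18 for endothelial markers. The smallest adjusted p with an estimated correlation was that of the myeloid markers (0.33). The p53 targets had a median of -0.07 and did not pass.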

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

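The tests on the third array and on the number of calls were chosen after the results were seen; the interaction tests were planned. Cyp1b1, Slc38a4 and Dglucy differed in their response to CKIα loss between mice without p53 and mice with both genes, by an interaction test with log2 differences of 2.72, 2.98 and -2.45. With the preset correlation, camera also found a difference for 8 lists, with medians of 1.10 for Wnt targets, 1.12 for crypt base markers, 1.16 for Paneth markers, 1.00 for cell cycle, 0.96 for DNA damage, -0.40 for p53 targets, -0.53 for xenobiotic genes and -1.03 for absorptive markers. For p21 it found 12 lists, with medians of 0.32 for Wnt targets, 0.49 for p53 targets, 0.87 for cell cycle, 0.74 for DNA damage, 0.71 for crypt base and 0.67 for Paneth markers. The others were negative: -0.63 for interferon genes, -0.42 for absorptive, -0.43 for goblet, -0.32 for enteroendocrine, -0.78 for fibroblast and -0.96 for lymphocyte markers. None of these 20 list differences held with an estimated correlation. That version passed 0 of the 21 lists in every comparison, also in CKIα KO against CKIα Het without p53, where limma called 2981 genes. As it was not simulated, its power is not known, and its failure does not show that a list is unchanged.

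The third array titled CKIα KO/p53 KO, used in no comparison, had Ccng1 at 11.22 and Eda2r at 6.07, above every CKIα Het/p53 KO array, while the CKIα KO/p53 KO arrays had Ccng1 at 9.06 and 8.91 and Eda2r at 3.21 and 3.25. A mixture of cells with and without p53 would put p53 targets between the groups, but those that separate CKIα KO/p53 KO (0) from CKIα KO (1) had a median position of 1.17, and poor quality would lower its correlations, but its highest with another array, CKIα KO replicate 2, was 0.986, within the range between replicates (0.971 to 0.990). It also stays open that p53 is active in this sample, as its genotype and source labels would give: 21 of 27 p53 targets lay closer to CKIα KO than to CKIα KO/p53 KO, against 56.4% of all genes. That share is not particular to p53 targets, since 12 of 14 goblet and 9 of 10 endothelial markers, 10 of 12 destruction complex and 16 of 21 xenobiotic genes lay closer to CKIα KO too. This may mean that the title rather than the genotype label is wrong, and the sample was not moved to another group.

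CKIα KO against CKIα Het gave 4 calls with both genes present and 2981 without p53. A larger spread between replicates could not act through the standard error, because the fit pools the spread of a gene over the 6 groups. Axin2, for one, had a standard error of 0.23 in both comparisons. The ratio of the replicate SDs of these comparisons was 1.00, so their own replicates were spread alike, which does not test the number of calls. A weak CKIα KO replicate 1 stays open: without that array 64 genes were called, but the comparison without p53 had 1321 without CKIα KO/p53 KO replicate 1, 251 without its replicate 2, and 20 and 655 without CKIα Het/p53 KO replicates 1 and 2, so which array is left out decides what 64 is set against. The changes as estimated were smaller with both genes present than without p53. Over all genes the median absolute log2 fold change was 0.149 and 0.292, and 320 and 1506 genes exceeded 2-fold. Whether the same genes change less in the mice themselves stays open. The 330 genes called without p21 had a median change in their direction of 0.38 with both genes and 0.93 without p53, a ratio of 0.41. This ratio was 0.30 with CKIα KO replicate 1 alone and 0.53 with replicate 2 alone (0.35 and 0.67 from means), so its size depends on the array. That p53 and p21 hold back the response is a biological candidate explanation that these groups name. Gene by gene, the interaction tests called a different CKIα effect for 3 genes for p53 and for 0 genes for p21. Their standard errors are larger than those of a single comparison (0.33 against 0.23 for Ccng1 in the p53 interaction). The few calls therefore do not show that few genes differ.

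Probe set 10443463, which the annotation gives to 2 genes, the knocked-out Cdkn1a being 1 of them, entered no gene test. Its signal cannot be split between the 2 genes. It was lower in CKIα Het/p21 KO than in CKIα Het by a log2 of -3.66 ± 0.30 (adjusted p = 0.00736). It lay between 5.52 and 5.86 on the 4 p21 knockout arrays and between 8.68 and 10.3 on the other arrays, the third array included. This is the pattern that the labelled p21 knockout would give, although a fall of the other gene on the same arrays cannot be told apart. Among 10408 probe sets outside the tested genes, 68 were higher and 21 lower in CKIα KO/p53 KO than in CKIα Het/p53 KO.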

How the results depend on the processing

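All alternatives were planned. Of 21 counts, all 21 stayed within 1.5 times with an intensity trend, 17 without the filter, 16 after quantile normalization, 16 with the replicate block and 13 with the third array. Without the filter, the comparison without p21 had 126 higher and 37 lower, the p53 interaction 1 higher, and 103 genes were shared between comparisons. After quantile normalization CKIα KO against CKIα Het had 2 higher, the comparison without p21 143 higher, the p53 interaction 2 lower, CKIα Het/p21 KO against CKIα Het 1 lower, and 139 were shared. Differences between replicates 1 and 2, correlated across genes over 15 pairs of groups, had a median r of 0.07 (-0.16 to 0.25, 5 above 0.1), so the numbers were not shown to pair the arrays, although they part them by sex-linked genes. With the replicate number as a block CKIα KO against CKIα Het had 2 higher, the p53 interaction 1 higher, CKIα KO/p53 KO against CKIα KO 218 higher and 120 lower, and CKIα KO/p21 KO against CKIα KO 1 lower. With the third array, CKIα KO against CKIα Het had 2 higher, the comparison without p21 77 higher and 31 lower, the p53 interaction and CKIα KO/p53 KO against CKIα KO 0 higher and 0 lower, and 67 were shared. The cause was not tested, except that without the filter more genes were tested, and that the third array changed the common estimate of the spread.

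Leaving out 1 array left a group with 1 sample, which was assumed to vary like the other groups, and fewer degrees of freedom. Higher and lower counts then ran from 0 to 57 and 0 to 7 for CKIα KO against CKIα Het, from 0 to 1695 and 0 to 1082 without p21, from 10 to 869 and 10 to 452 without p53, and from 1694 to 3032 and 960 to 1839 averaged. For the p53 interaction they ran from 0 to 17 and 0 to 3, and for the p21 interaction from 0 to 74 and 0 to 34. For CKIα KO/p53 KO against CKIα KO they ran from 3 to 170 and 1 to 71, for CKIα KO/p21 KO against CKIα KO from 2 to 761 and 0 to 387, for CKIα Het/p21 KO against CKIα Het from 0 to 4 and 0 to 2, and for CKIα Het/p53 KO against CKIα Het lower counts from 0 to 2. The shared genes ran from 3 to 1963.

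Of 310 values of named genes, 306 kept their direction and side of the threshold with the trend, 288 without the filter, 292 after quantile normalization, 297 with the block and 245 with the third array, and of 1936 without 1 array 1491 did. Csnk1a1 reversed without p21 after quantile normalization (-0.06 against 0.14), and without p53 ran from -0.16 to 0.06 when 1 array was left out. Neither passed. Of 96 list calls, 93 stayed after quantile normalization, 95 with the block, 90 with the third array and 0 with an estimated correlation. Quantile normalization moved the median of all genes by -0.042 to 0.041. Signal near the background limits what can be seen for dim genes.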

Other observations

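The tests on cell composition were chosen after the results were seen, while the splits of the arrays and the tests of neighbouring genes were planned. Some members of the lipid and xenobiotic lists, neither of which held its call with an estimated correlation (adjusted p = 0.674 and 0.483), passed on their own without p53. Sqle, an enzyme of cholesterol synthesis, rose (log2 1.43), while Abcg5, a sterol exporter, fell (-1.94), as did Apoc3, an apolipoprotein (-2.72), Dgat1, a triglyceride enzyme (-1.14), and the glutathione transferase Gstm3 (-2.29). In CKIα KO against CKIα Het, Sqle was at 1.40 ± 0.28 (adjusted p = 0.152) and Lyz2, a myeloid marker, at -1.65 ± 0.32 (adjusted p = 0.129), and neither passed. Without p53 the stem cell factor Msi1 (1.48), the receptor ligase Znrf3 (1.75) and Cdca7 (1.58) rose.

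Without p53, 13 of 23 absorptive markers fell and 6 of 14 crypt base markers and 19 of 29 cell cycle genes rose in CKIα KO, although none of these lists held its call with an estimated correlation (adjusted p = 0.48, 0.483 and 0.48). A lower share of absorptive enterocytes alone would raise the markers of every other cell type, but averaged over backgrounds 9 of 14 goblet and 15 of 19 enteroendocrine markers fell, and the medians of these and of the tuft list were below 0, the highest of them -0.17 for tuft cells. A larger share of crypt cells would raise crypt base and cell cycle lists with the Wnt targets. With both genes present the higher of their medians was 0.12 of that of the Wnt targets, which decides nothing: the Wnt median was 0.40, and members of the crypt base list had an SD of 0.71 and of the cell cycle list of 0.27. Without p53 it was 0.62, from the cell cycle median of 1.05 against 1.70 for the Wnt targets, and the crypt base median was 0.99. As 5 of the 14 crypt base markers are also Wnt targets, part of the rise of that list with the Wnt targets was fixed in advance. A larger share of crypt cells may contribute there. Wnt activity within each cell would raise these lists too and was not tested apart from a larger share of crypt cells.

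For the average over backgrounds, 100 of 462 possible splits of the 12 arrays into 6 and 6 were fitted. The model was additive in background, unlike the fit behind the counts given for this average. Only 1 of the 100, the real split, gave its 3401 calls, which argues against chance. With the real split among the 100 this share could not be smaller, so chance is not excluded. The highest of the others gave 3093 and placed 10 of the 12 arrays as the real one does.

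A knockout made in another strain carries its neighbouring genes along. Over the 40 tested genes nearest to Cdkn1a, the median absolute p21 effect was 0.176 against 0.112 over the genome, at the 98.2 percentile of 10000 random windows of neighbouring genes. Rab44, with 0 protein-coding genes between it and Cdkn1a, rose most of them, so its rise may come from the altered locus itself. The 40 genes nearest to Trp53 had a median absolute p53 effect of 0.101 against 0.132, at the 11.2 percentile, which argues against such an effect on most of them. A median cannot exclude it for a few genes, and Chd3 was at -1.09 and Sat2 at 0.71.

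Genes of the sex chromosomes, chosen after their values were seen, parted the arrays by replicate number. Eif2s3y, on the Y chromosome, lay between 8.35 and 8.77 on the 6 replicate 1 arrays, at 8.05 on the third array and between 3.09 and 3.69 on the 6 replicate 2 arrays. Uty and Kdm5d parted them in the same way. Replicate 1 arrays and the third array thus had the pattern of male mice, and replicate 2 arrays that of female mice. Sex cannot be told apart from any other difference between replicates 1 and 2. On the first principal component, replicate 2 minus replicate 1 was 25.6 in CKIα KO, 47.1 in CKIα KO/p21 KO and 8.20 in CKIα KO/p53 KO, and 1.10, -10.6 and 1.80 in CKIα Het, CKIα Het/p21 KO and CKIα Het/p53 KO. With 1 array of each kind in a group, a comparison of single groups within either kind has no replicates. The average over backgrounds was not fitted within a kind. Fits with the replicate number as a block remove only a shift that all groups share, and these differences were not alike between groups. In every background the difference was larger in CKIα KO than in CKIα Het. The CKIα effect on this component was thus larger between replicate 2 arrays than between replicate 1 arrays, which was not tested further.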
